A study of Homo sapiens with 8 samples.

How the data were processed

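Polyadenylated RNA from 8 samples of THP1-derived macrophages was sequenced, 2 for each of 4 transfected RNAs (untreated and PNGase F-treated small RNA of HeLa cells, and an unmodified and an acp3U-8C-modified synthetic tRNA fragment). RNA was purified with a Zymo column kit and made into libraries with a stranded Illumina TruSeq mRNA kit, per the labels' protocols. The upstream tools were HISAT2 2.2.1, SAMtools 1.9 and StringTie 2.1.3, per the submitters' processing notes, which also name the builds GRCh38 and GRCm38 without a role. The annotation release, the strand setting and any read filter are not given in the sources used here. The authors deposited 1 table of FPKM per gene and library, that is, values scaled to the length of each gene and to the mapped fragments of each library.

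The table held 60664 genes, of which 20055 carried no symbol, and 1506 of these were named from the GENCODE table by Ensembl identifier. Columns were matched to samples by the library name in the labels, and no column was left unmatched. Of all identifiers 96.3% were found in GENCODE release 29 (GRCh38), as were 99.5% of the genes tested, and positions are given from that annotation, 1-based. Where several entries share a symbol, the entry with the highest mean FPKM stood for the gene in the lists. Counts and read totals were not used here, so total depth is unknown and no counting interval is given. The relative depth of the libraries was estimated from the most frequent ratio of low values between library pairs (FPKM 0.01 to 0.2), which should step with 1 read. Of the 21 pairs without the first library, 14 matched the ratio implied by it within 0.005 log2 units.

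Values were tested as log2(FPKM + 1) for the 13223 genes with at least 1 FPKM in at least 2 of the 8 libraries. A model of 4 group means was fitted to all 8 libraries in limma 3.58.1 (R 4.3.3), with moderated variances that followed a trend in mean expression, so that the spread was estimated on 4 residual degrees of freedom. Calls used a Benjamini-Hochberg adjusted p under 0.05. The comparisons were PNGase F-treated against untreated small RNA, acp3U-8C against unmodified fragment, unmodified fragment against untreated small RNA, and the difference of the first 2 effects. Exact permutation of 2 against 2 libraries cannot give a two-sided p under 0.333. Chance separates 2 against 2 libraries without overlap for 33.3% of genes. Of all genes tested, 79.7%, 79.4% and 64.4% were so separated in the PNGase F, acp3U-8C and reference comparisons. Every gene called in these 3 comparisons was too, which a call nearly requires, so it adds no separate support.

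Data were simulated from the gene means over all 8 libraries and the moderated spread of each gene. For each comparison, 100 genes were changed by 0.5 log2 units, 100 by 1, and the others were unchanged. The procedure recovered 85% of genes changed by 0.5 and 99% of those changed by 1 in the PNGase F comparison. These rates were 83% and 97% in the acp3U-8C comparison, and 88% and 100% in the comparison of the reference RNAs. False calls numbered 12 among 12474 unchanged genes, 4 among 12479 and 7 among 12468. The simulation held far fewer changed genes than were called in the data, and no shift of most genes. The changed genes were drawn only from genes above a set mean expression, and recovery was not split by expression level. These rates therefore do not cover low genes.

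Gene lists (34, for antiviral, inflammatory, antigen presentation, stress and metabolic genes and for markers of other cell types) were tested with limma's camera at a preset inter-gene correlation of 0.01 where at least 5 members were tested, with Benjamini-Hochberg adjustment over the 32 lists of a comparison. The lists of type I and III interferon genes and of lymphocyte markers had fewer than 5 tested members and were not tested as lists. Lists, comparisons, the main model, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 largest increases and decreases per comparison (5 for the reference RNAs) among called genes whose libraries did not overlap and whose mean reached 1 FPKM in a group, the 4 members with the largest moderated statistic in each list that passed camera, and the panel IFNB1, IL6, TNF, IL1B, CXCL10, CCL5, IFIT1, ISG15, MX1, TLR3, TLR7, TLR8, MERTK and CD36. Values of genes with near-identical copies (HSPA1A and HSPA1B, CCL3 and CCL3L1, HLA-DRB1 and HLA-DRB5, AKR1C2 and AKR1C3, histone genes and mitochondrial genes) and of overlapping or antisense genes are uncertain, because the authors' counting could have split reads between them.

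The alternatives were pseudocounts of 0.1 and 0.01, no filter and a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, rescaling to TPM, only the 4 libraries of a comparison, moderation without trend or with robust settings, library weights, a replicate block, each library left out in turn, and for lists an estimated correlation and the rotation test fry. Median-of-ratios factors, computed over genes passing the filter and above 0 in every library, ran from 0.914 (acp3U-8C replicate 1) to 1.08 (untreated small RNA replicate 1). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.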

Results

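Messenger RNA was profiled in macrophages derived from THP1, a human monocytic leukaemia line, that had been treated with phorbol ester for 24 hours and collected 6 hours after transfection with 1 of 4 RNA preparations. The first preparation was small RNA from HeLa cells, a human cervical carcinoma line. The second was the same kind of small RNA after PNGase F, an enzyme that removes N-linked glycans. The third was a synthetic tRNA fragment of 18 nucleotides without modification, and the fourth was such a fragment carrying the acp3U-8C modification, where acp3U is 3-(3-amino-3-carboxypropyl)uridine. Each group held 2 libraries, and no untransfected or mock-transfected sample was analysed here, so each treated RNA was compared with its own untreated or unmodified counterpart.

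The deposited values were FPKM for 60664 genes, which summed to between 354282 and 378804 per library, with 23811 to 27403 genes above 0. Total read numbers were unknown. Steps between the low FPKM values placed the depth of the other libraries at 54.2% (acp3U-8C replicate 1, the least certain estimate) to 108% (PNGase F replicate 1) of the depth of the first untreated small RNA library. Replicates correlated at Pearson r of 0.994 to 0.995 across the genes tested, which are not independent replicates, and the first principal component held 64.8% of the variance and separated the PNGase F and acp3U-8C libraries from their 2 reference groups. Differences are given on the log2(FPKM + 1) scale, which understates the change of low genes. The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

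The first comparison asked how the response of the recipient macrophages differed between PNGase F-treated and untreated small RNA. No group labelled as mock-digested small RNA was analysed here, so removal of N-glycans cannot be told apart from other effects of the treatment. An interferon response stood out in cells given PNGase F-treated small RNA. CXCL10, a chemokine induced by interferon (ENSG00000169245, chromosome 4, 76021117 to 76023497, GRCh38), rose from 6.83 ± 0.0241 to 499.9 ± 12.2 FPKM (mean ± SD, n = 2), and IFNB1, which encodes interferon beta (ENSG00000171855, chromosome 9, 21077105 to 21077963), rose from 0.639 ± 0.255 to 39.0 ± 0.356 FPKM. All 45 tested members of the interferon-stimulated antiviral list rose, with a median log2 difference of 1.73. TNF, an inflammatory cytokine, moved the other way, from 10.2 ± 1.36 to 7.28 ± 0.295 FPKM.

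The largest increases with PNGase F-treated small RNA were those of CXCL10 (log2 difference 6.00), CCL8 (5.67), CCL2 (5.58), CXCL11 (4.97), IFNB1 (4.62), GBP1 (4.36), GBP4 (4.27), CD274 (4.23), SECTM1 (4.06) and IFNL1 (3.72). CCL2 and CCL8 attract monocytes, CD274 encodes the checkpoint ligand PD-L1, and IFNL1 encodes a type III interferon. Their adjusted p-values in limma with Benjamini-Hochberg adjustment ran from 5.27e-09 for CXCL10 to 7.76e-07 for IFNL1. Among the named interferon-stimulated genes, IFIT2 rose by 3.64, IFIT1 by 2.40, ISG15 by 2.06, MX1 by 2.70 and HERC5 by 3.69. The list as a whole passed camera with an adjusted p of 3.78e-56, and missed the threshold with an adjusted p = 0.0539 with an estimated correlation.

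Many sensors and signalling genes of the antiviral response rose as well, while others fell. In the cytosolic nucleic acid sensing list 11 of 16 genes rose and 2 fell, among them the RNA sensors DDX58 (also called RIGI; 2.05) and IFIH1 (2.25), and AIM2 (2.61) and IFI16 (1.68), which bind DNA (camera adjusted p = 9.2e-10; adjusted p = 0.0537 with an estimated correlation). In the interferon regulatory and JAK-STAT list 9 of 16 rose and 4 fell, led by IRF1 (2.24), STAT2 (1.61) and SOCS3 (2.38) (camera adjusted p = 1.82e-06; adjusted p = 0.0925 with an estimated correlation). In the list of endosomal RNA sensing by Toll-like receptors 8 of 18 rose and 7 fell, against 9 and 1 with median-of-ratios scaling. Examples were MYD88 at 1.37, TASL at 1.33, UNC93B1 at 0.72 and TLR7, a receptor for single-stranded RNA, at 1.24 (camera adjusted p = 0.00814; adjusted p = 0.161 with an estimated correlation and 0.0978 with the filter of 5 FPKM). TLR8 rose by 1.17, from 0.404 to 2.17 FPKM. TLR3 lay below the expression filter at 0.0788 and 0.239 FPKM.

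Antigen presentation genes of MHC class I followed. In the MHC class I list 17 of 20 genes rose and none fell, including the peptide transporters TAP1 (2.44) and TAP2 (1.26), NLRC5 (1.56) and the proteasome subunit PSMB9 (2.01), with a camera adjusted p of 8.22e-17 that held with an estimated correlation (adjusted p = 0.0355). Macrophage differentiation markers also held with an estimated correlation (camera adjusted p = 9.2e-10; adjusted p = 0.0355 with an estimated correlation). In that list 12 of 18 rose and 1 fell. Examples were FCGR1A, a high-affinity Fc receptor, at 1.91, SIGLEC1 at 1.81, CEBPB at 1.64 and the scavenger receptor CD163 at 2.07. In the inflammasome and pyroptosis list 6 of 11 rose and 2 fell. Examples were CASP4 at 1.69, CASP1 at 1.61, GSDMD at 1.15 and CARD16 at 1.36 (camera adjusted p = 0.000186; adjusted p = 0.0925 with an estimated correlation).

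Inflammatory genes moved in both directions. In the cytokine list 5 of 14 rose and 3 fell (camera adjusted p = 0.00187; adjusted p = 0.0925 with an estimated correlation). IL1RN, the interleukin 1 receptor antagonist, rose by 2.00, IL27 by 1.67, CSF1 by 0.90 and PTGS2 by 1.42, while TNF fell by 0.43 (limma, Benjamini-Hochberg adjusted p = 0.00344). IL1B stood at 349 and 369.6 FPKM, a log2 difference of 0.09 that was not called in limma (Benjamini-Hochberg adjusted p = 0.17) but was called under median-of-ratios scaling (0.29) and on rescaling to TPM (0.13). IL6 was listed at 0 in both untreated small RNA libraries and at 1.21 and 1.28 FPKM in the PNGase F libraries. In the chemokine list 10 of 18 rose and 2 fell, and CXCL9 (2.76) and CCL5 (0.50) were among those that rose (camera adjusted p = 1.51e-06; adjusted p = 0.152 with an estimated correlation). In the list of NF-kB feedback and target genes 12 of 27 rose and 7 fell. Examples were GCH1 at 2.94, BCL3 at 1.79, CD40 at 1.75 and ICAM1 at 0.84 (camera adjusted p = 0.000395; adjusted p = 0.209 with an estimated correlation).

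Other lists that passed camera upward held mixtures of changes. Of the immediate early genes 14 of 24 rose and 5 fell. Examples were ATF3 at 1.01 and JUN at 0.69 against DUSP2 at -1.43 and FOS at -0.61 (adjusted p = 0.0684 with an estimated correlation). Of the alternative activation genes 5 of 9 rose and 1 fell. Examples were CLEC10A at 1.42, TGM2 at 0.67 and the lipid regulator PPARG at -0.55 (adjusted p = 0.0925 with an estimated correlation). Of the dendritic cell markers 6 of 8 rose and 1 fell, and the leading members were IDO1, a tryptophan-degrading enzyme (2.64), BATF3 (1.57) and TCF4 (0.66) (adjusted p = 0.202 with an estimated correlation). Of the heat shock proteins 5 of 14 rose and 2 fell. Examples were DNAJA1 at 1.00 and HSPA6 at 0.94 (adjusted p = 0.357 with an estimated correlation). Of the apoptotic cell uptake genes 6 of 19 rose and 4 fell. Examples were AXL at 1.15, GAS6 at 0.74 and THBS1 at 1.09 (adjusted p = 0.16 with an estimated correlation). MERTK, an uptake receptor of that list, rose by 0.22 (limma, Benjamini-Hochberg adjusted p = 0.0222), a call lost without untreated small RNA replicate 1 (0.18) or PNGase F replicate 2 (0.16), or without a filter (0.22). The scavenger receptor CD36 was not called at 109 and 108 FPKM, while median-of-ratios scaling called it higher (0.19). The uptake list no longer passed without PNGase F replicate 1 (0.15 above the median gene, adjusted p = 0.0718) or replicate 2 (0.15 above it, adjusted p = 0.0916), with the filter of 5 FPKM (adjusted p = 0.0996) or with quantile normalization (adjusted p = 0.081). Of the replication-dependent histones 2 of 7 rose, H2AC18 (0.63) and H4C14 (0.69), and H1-2 (-0.30) and H2BC21 (0.27) were not called (adjusted p = 0.161 with an estimated correlation). The histone list no longer passed without PNGase F replicate 1 (adjusted p = 0.07), where H1-2 was called (-0.43), without a filter (adjusted p = 0.0889) or with median-of-ratios scaling (adjusted p = 0.0543).

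Proliferation and cholesterol genes were lower. In the proliferation list 20 of 29 fell and none rose, including AURKA (-0.81), CDC20 (-0.55), MCM2 (-0.45) and CENPF (-0.57) (camera adjusted p = 0.00567; adjusted p = 0.0925 with an estimated correlation). In the cholesterol biosynthesis list 13 of 20 fell and none rose, including LSS (-0.66), SQLE (-0.46), MVK (-0.61) and INSIG1 (-0.34) (camera adjusted p = 0.0132; adjusted p = 0.202 with an estimated correlation). Under median-of-ratios scaling 6 proliferation genes and 5 cholesterol genes fell, 1 cholesterol gene rose, and the cholesterol list no longer passed (camera adjusted p = 0.302). Large decreases of single genes were those of STARD4-AS1 (-2.28), PHLDA3 (-1.73), DUSP7 (-1.59), ITPKB (-1.48), FRMD4A (-1.44) and the phosphatase gene DUSP2 (-1.43), with limma Benjamini-Hochberg adjusted p-values from 5.25e-07 for DUSP7 to 7.33e-05 for PHLDA3. ADAMTS1, which encodes a secreted protease, fell from 17.8 to 5.68 FPKM. ENSG00000284292 (-2.55), ENSG00000269711 (-1.61) and ENSG00000269970 (-1.43) overlap ARPC1A and ARPC1B, MCEMP1 and TRAPPC5, and PTGS1, and their values are uncertain. STARD4-AS1 is annotated as an antisense transcript, and its value is also uncertain because the strand setting of the counting is not given in the sources used here.

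Across all 13223 genes tested, limma called 6920 at a Benjamini-Hochberg adjusted p under 0.05, 1653 higher and 5267 lower with PNGase F-treated small RNA, and 412 of the higher and 84 of the lower genes differed by at least 1 log2 unit. The median gene was shifted by -0.19, and 73.8% of the genes lay below 0. With median-of-ratios scaling, which brought the median to -0.02, 4562 genes were called, 2538 higher and 2024 lower. The share of higher calls therefore depended on the scaling (23.9% as deposited and 55.6% scaled), and relative to the median gene the interferon-stimulated list stood at 1.92, the MHC class I list at 0.74, the proliferation list at -0.12 and the cholesterol list at -0.05. Camera passed 18 of 32 lists, 16 upward and 2 downward, and 2 of these held with an estimated correlation. With median-of-ratios scaling 19 passed, with lysosome, the unfolded protein response and mitochondrially encoded mRNAs added upward and the cholesterol and histone lists lost. Scaled counts of genes that rose and fell were 10 and 0 for JAK-STAT, 16 and 4 for NF-kB, 7 and 0 for inflammasome, 17 and 2 for immediate early, 8 and 0 for heat shock and 9 and 2 for uptake genes. The 14 lists that did not pass were MHC class II, liver X receptor targets, lysosome, N-glycosylation and RNA transport, the integrated stress response, the unfolded protein response, metallothioneins and NRF2 targets, hypoxia and glycolysis, p53 targets, ribosomal proteins, mitochondrially encoded mRNAs, oxidative phosphorylation, epithelial markers, and granulocyte and mast cell markers. Adjusted over the list alone, the counts of the passing lists were equal except for 3 chemokines that fell, 5 uptake genes that fell, 14 cholesterol genes that fell, 21 proliferation genes that fell, 15 immediate early genes that rose, 2 dendritic cell markers that fell, and 6 alternative activation genes that rose with 2 that fell.

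**Figure D1:**
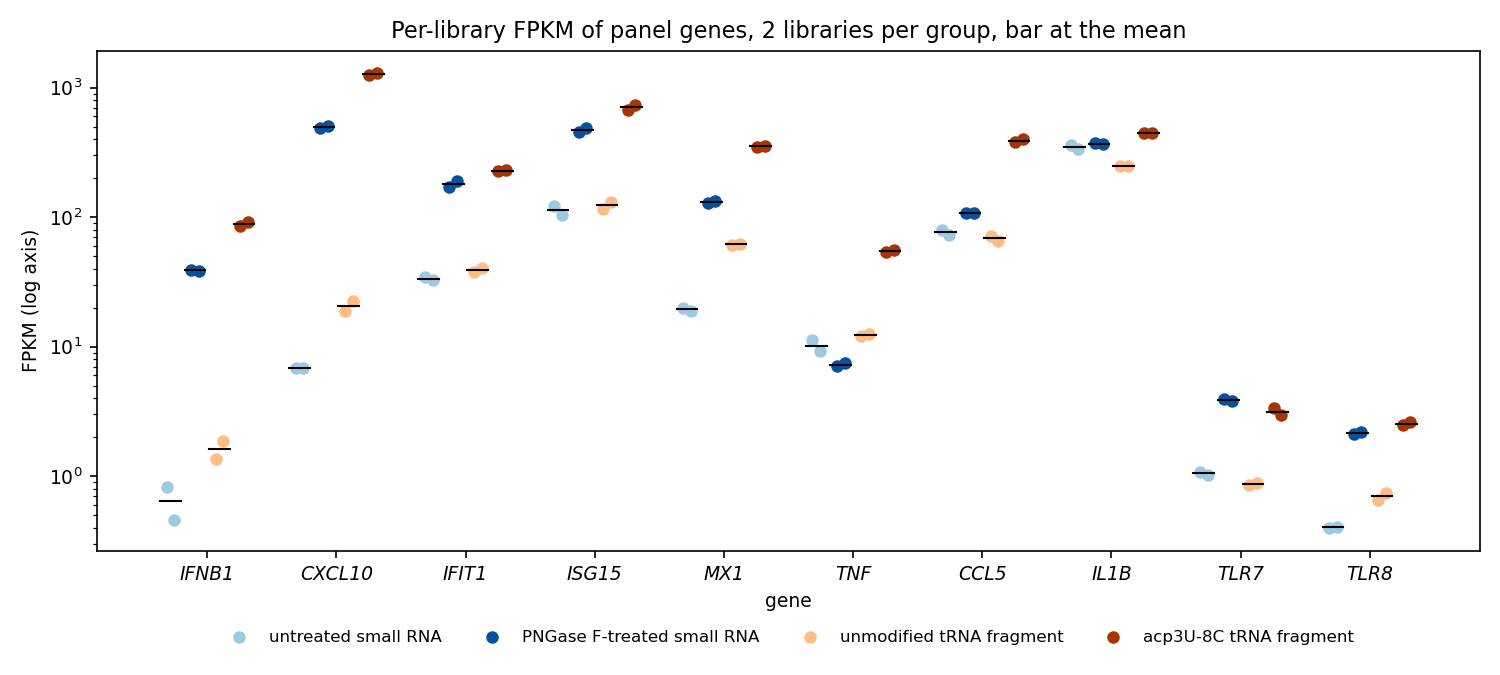
FPKM of 10 panel genes on a log axis, with 1 point per library, 4 groups of 2 libraries and a bar at each group mean. IFNB1 rose from 0.639 to 39.0 FPKM with PNGase F-treated small RNA and from 1.62 to 89.3 FPKM with the acp3U-8C fragment, while TNF rose with the acp3U-8C fragment to 54.7 FPKM and lay at 7.28 FPKM with PNGase F-treated small RNA.

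The second comparison asked how the response differed between the acp3U-8C and the unmodified 18-nucleotide synthetic fragment. The modification cannot be told apart from a difference in the amount transfected, which is not given in the sources used here. The modified fragment raised interferon, chemokine and inflammatory cytokine transcripts together. CXCL10 rose from 20.7 ± 2.67 to 1268 ± 27.3 FPKM (mean ± SD, n = 2), IFNB1 from 1.62 ± 0.360 to 89.3 ± 4.57 FPKM, and TNF (ENSG00000232810, chromosome 6, 31575567 to 31578336) from 12.3 ± 0.408 to 54.7 ± 1.29 FPKM. IL6 (ENSG00000136244, chromosome 7, 22725884 to 22732002) was listed at 0 and 0.0212 FPKM in the unmodified fragment libraries and at 7.14 and 6.94 FPKM in the acp3U-8C libraries. As with PNGase F-treated small RNA, 45 of 45 interferon-stimulated antiviral genes rose, with a median of 1.83 (camera adjusted p = 7.92e-50), and this call held with an estimated correlation (adjusted p = 0.0445).

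The largest increases with the acp3U-8C fragment were those of CCL8 (6.11), CXCL11 (5.98), CXCL10 (5.87), IFNL1 (5.52), CCL2 (5.46), IFNB1 (5.11), IDO1 (4.80), GCH1 (4.64), HERC5 (4.60) and GBP4 (4.54), with limma Benjamini-Hochberg adjusted p-values from 3.62e-09 for CXCL10 to 7.45e-08 for IFNL1. GCH1 makes the first committed step of tetrahydrobiopterin synthesis. Of the chemokines 13 of 18 rose and none fell, with a median of 2.32, CXCL9 at 4.00 and CCL5 at 2.48 (camera adjusted p = 8.54e-14; adjusted p = 0.0675 with an estimated correlation). Of the inflammatory cytokines 10 of 14 rose and 1 fell, among them IL27 (3.02), TNF (2.06), PTGS2 (2.19) and IL1B (0.84), and the list held with an estimated correlation (camera adjusted p = 6.88e-08; adjusted p = 0.0364 with an estimated correlation). Of the NF-kB feedback and target genes 19 of 27 rose and 5 fell. Examples were NFKBIZ at 1.68, CD40 at 2.14 and BCL3 at 1.30 (camera adjusted p = 1.65e-09; adjusted p = 0.0825 with an estimated correlation). Of the immediate early genes 16 of 24 rose and 4 fell. Examples were DUSP5 at 1.19, ATF3 at 1.15, JUNB at 1.00 and KLF4 at 0.92, and the list held with an estimated correlation (camera adjusted p = 4.33e-08; adjusted p = 0.0364 with an estimated correlation).

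Many sensing genes and most MHC class I presentation genes rose with the modified fragment too. In the cytosolic nucleic acid sensing list 11 of 16 rose and 3 fell. Examples were AIM2 at 3.02, IFIH1 at 2.59, DDX58 at 2.23 and IFI16 at 1.66 (camera adjusted p = 1.26e-09; adjusted p = 0.0364 with an estimated correlation). In the MHC class I list 19 of 20 rose and none fell. Examples were TAP1 at 2.30, PSMB9 at 1.94, NLRC5 at 1.23 and TAP2 at 0.93 (camera adjusted p = 5.36e-16; adjusted p = 0.0364 with an estimated correlation). Of the macrophage differentiation markers 13 of 18 rose and 2 fell. Examples were SIGLEC1 at 1.63, CEBPB at 1.60, FCGR1A at 1.22 and CSF1R at 0.64 (camera adjusted p = 1.89e-08; adjusted p = 0.0364 with an estimated correlation). The interferon regulatory and JAK-STAT list had 10 of 16 genes that rose and 3 that fell. Examples were IRF1 at 1.87, STAT2 at 1.37 and SOCS3 at 1.92 (camera adjusted p = 4.88e-07; adjusted p = 0.0707 with an estimated correlation). The inflammasome and pyroptosis list had 8 of 11 that rose and 3 that fell. Examples were CASP1 at 1.79, CASP4 at 1.75, CARD16 at 1.56 and GSDMD at 1.09 (camera adjusted p = 1.67e-05; adjusted p = 0.0714 with an estimated correlation). The endosomal RNA sensing list had 7 of 18 that rose and 6 that fell. Examples were MYD88 at 1.13, TASL at 0.93, UNC93B1 at 0.83 and TLR7 at 1.15 (adjusted p = 0.141 with an estimated correlation and 0.0501 with the filter of 5 FPKM), and TLR8 rose by 1.06.

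Smaller upward lists passed camera without holding under an estimated correlation. They were the dendritic cell markers, with 6 of 8 that rose and 1 that fell, LAMP3 at 1.32, BATF3 at 2.00 and CLEC10A at 1.04 (adjusted p = 0.153 with an estimated correlation), and the alternative activation genes, with 4 of 9 that rose and 2 that fell, CD163 at 1.27 and PPARG at -0.84 (adjusted p = 0.153 with an estimated correlation). In the unfolded protein response list 5 of 20 rose and 3 fell, against 15 and 1 with median-of-ratios scaling. Examples were XBP1 at 1.33, DNAJB9 at 0.93 and EDEM1 at 0.55 against ERN1 at -0.81 (adjusted p = 0.0971 with an estimated correlation). In the MHC class II list 3 of 9 rose and none fell, with the transactivator CIITA at 1.54, CTSS at 0.73 and HLA-DRA at 0.63 (adjusted p = 0.141 with an estimated correlation). No member of the granulocyte and mast cell list was called, and its leading values were 0.16 for CTSG, 0.14 for ELANE, 0.42 for S100A9 and -0.23 for TPSB2 (adjusted p = 0.285 with an estimated correlation). With median-of-ratios scaling 6 of the 8 rose and none fell, among them CTSG (0.38), ELANE (0.37) and S100A9 (0.58), and leaving out untreated small RNA replicate 1 or replicate 2 called CTSG and ELANE at the values above. CTSG was also called without unmodified fragment replicate 2 (0.22), and S100A9 without unmodified fragment replicate 1 (0.70). Some of these lists lost their call in other settings. The granulocyte list missed without PNGase F replicate 1 (adjusted p = 0.0516) or 2 (0.0522), unmodified fragment replicate 2 (0.123) or acp3U-8C replicate 2 (0.0771), with pseudocounts of 0.1 and 0.01 (0.0512 and 0.0566), the filter of 5 FPKM (0.0688), quantile normalization (0.193), moderation without trend (0.0613), library weights (0.0506) and fry (0.126). The alternative activation list missed without unmodified fragment replicate 2 (0.0837) or acp3U-8C replicate 2 (0.0519), with the filter of 5 FPKM (0.168) and quantile normalization (0.145). The MHC class II list missed without acp3U-8C replicate 1 (0.0501) or 2 (0.0533) and with the filter of 5 FPKM (0.186), and the unfolded protein response with quantile normalization (0.159).

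Proliferation and cholesterol genes were again lower. In the proliferation list 22 of 29 fell and none rose, with UHRF1 at -1.27, AURKA at -0.94, MCM2 at -0.72 and MCM4 at -0.65 (camera adjusted p = 0.00482; adjusted p = 0.0825 with an estimated correlation). In the cholesterol biosynthesis list 18 of 20 fell and 1 rose, with MVK at -1.11, LSS at -0.76, SQLE at -0.72 and INSIG1 at -0.47 (camera adjusted p = 0.00282; adjusted p = 0.141 with an estimated correlation). With median-of-ratios scaling 13 proliferation genes and 9 cholesterol genes fell, while 3 and 2 rose. DUSP7 (-1.84), ITPKB (-1.80), PHLDA3 (-1.66), ADORA2B (-1.62), C3orf80 (-1.62) and ADAMTS1 (-1.59) were large decreases of other genes, with limma Benjamini-Hochberg adjusted p-values from 2.04e-07 for DUSP7 to 6.9e-05 for PHLDA3. ENSG00000285779 (-4.29), RAB4B-EGLN2 (-2.27) and ENSG00000269970 (-1.61) overlap other genes on the same strand and are uncertain, and the first lost its call without unmodified fragment replicate 1 (-3.48), without a filter and with robust moderation. A CCDC39 entry with a second overlapping entry of the same name was listed at 0 in both acp3U-8C libraries, against a mean of 2.21 FPKM with the unmodified fragment. HLA-DRA of the class II list lost its call without unmodified fragment replicate 2 (0.45) or with a pseudocount of 0.01 (1.67). MERTK fell by 0.25 (limma, Benjamini-Hochberg adjusted p = 0.0113), a call lost with median-of-ratios scaling (-0.04), quantile normalization (-0.14) or TPM (-0.20) or without acp3U-8C replicate 2 (-0.21). CD36 was not called at 102 and 96.0 FPKM, while median-of-ratios scaling called it higher (0.14).

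In total limma called 7790 of the 13223 genes at a Benjamini-Hochberg adjusted p under 0.05, 1903 higher and 5887 lower with the acp3U-8C fragment, and 505 and 174 of them differed by at least 1 log2 unit. The median gene was shifted by -0.20. With median-of-ratios scaling 5602 genes were called, 2978 higher and 2624 lower, so the share of higher calls was 24.4% as deposited and 53.2% scaled. Relative to the median gene, the chemokine list stood at 2.52, the interferon-stimulated list at 2.03, the inflammatory cytokines at 0.99, the cholesterol list at -0.17 and the proliferation list at -0.25. Camera passed 18 of 32 lists, 16 upward and 2 downward, and 6 held with an estimated correlation. With median-of-ratios scaling 19 passed, with apoptotic cell uptake added upward. Scaled counts of genes that rose and fell were 12 and 0 for JAK-STAT, 13 and 0 for cytosolic sensing, 10 and 3 for endosomal sensing, 8 and 0 for inflammasome, 5 and 0 for MHC class II and 6 and 1 for alternative activation genes. The 14 that did not pass were apoptotic cell uptake, liver X receptor targets, lysosome, N-glycosylation and RNA transport, the integrated stress response, heat shock proteins, metallothioneins and NRF2 targets, hypoxia and glycolysis, p53 targets, ribosomal proteins, mitochondrially encoded mRNAs, oxidative phosphorylation, replication-dependent histones and epithelial markers. Adjusted over the list alone, the counts of the passing lists were equal except for 20 NF-kB genes that rose, 2 cholesterol genes that rose, 3 macrophage markers that fell and 17 immediate early genes that rose.

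**Figure D2:**
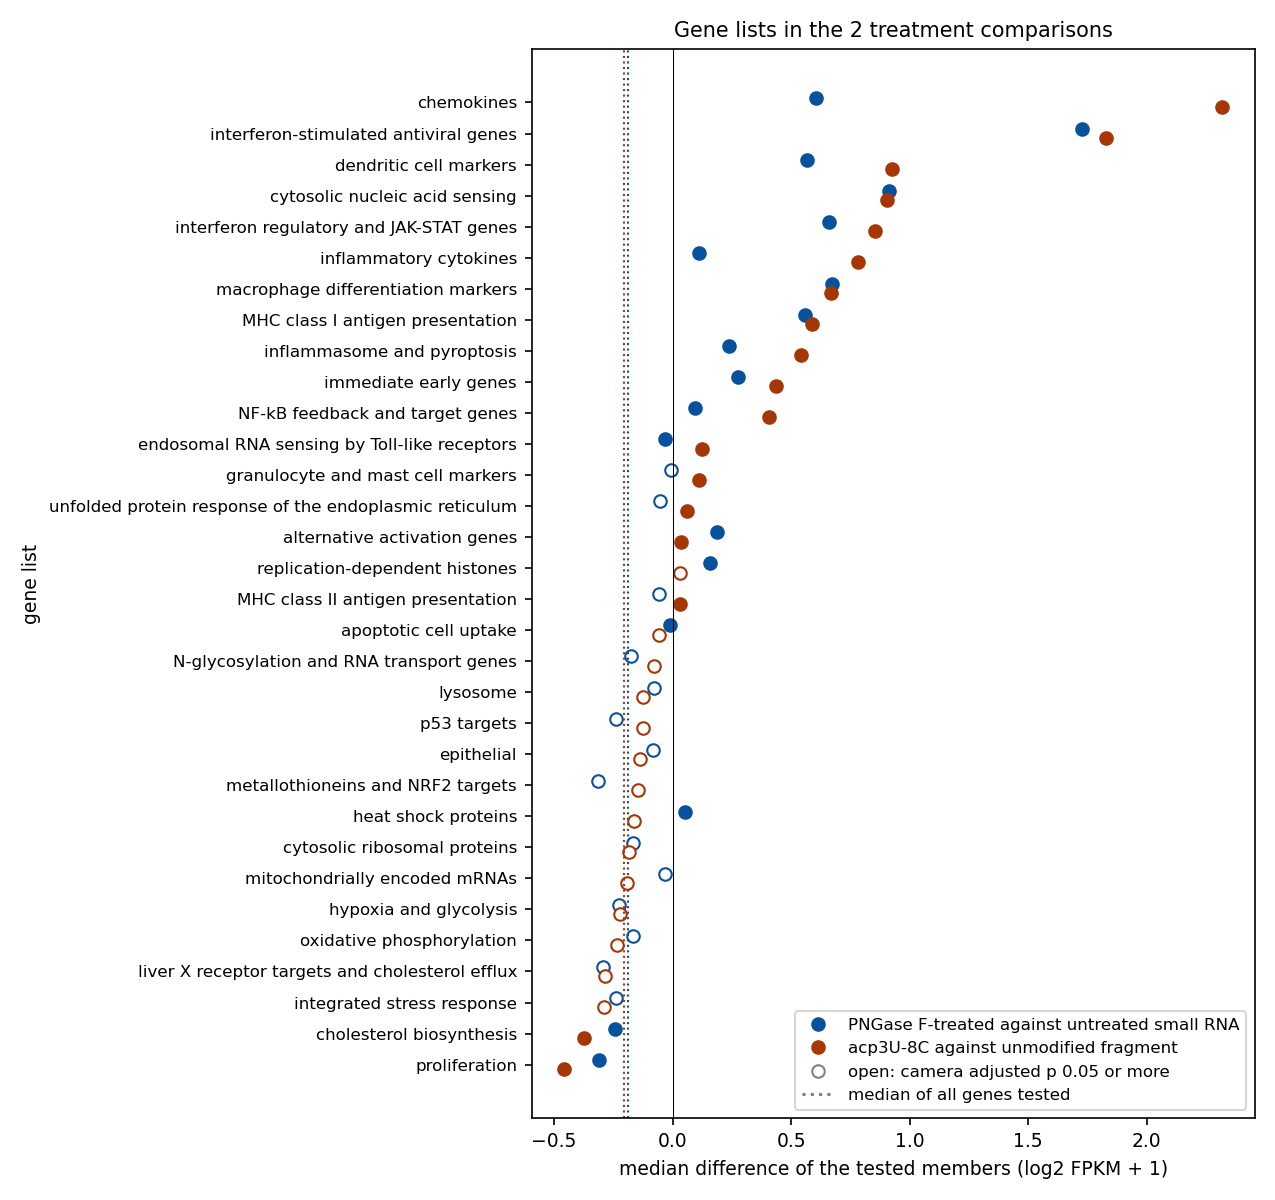
Median log2(FPKM + 1) difference of the tested members of 32 gene lists, with 1 point per list and comparison, filled where camera gave an adjusted p under 0.05, and dotted lines at the median of all genes tested. The chemokine list lay at 0.61 with PNGase F-treated small RNA and at 2.32 with the acp3U-8C fragment, and the interferon-stimulated list at 1.73 and 1.83.

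The third question was whether the 2 treatments moved the same genes. Of the 1653 genes higher with PNGase F and the 1903 higher with acp3U-8C, 1357 were shared, where independent lists would share 238, and 4103 were lower in both, where independent lists would share 2345. With median-of-ratios scaling 2062 were higher in both (572 from independent lists) and 1401 lower in both (402 from independent lists). Only 18 genes were called higher with PNGase F and lower with acp3U-8C, and 47 the reverse. The 2 comparisons share no libraries, and their log2 differences correlated across genes at Pearson r = 0.85 and Spearman rho = 0.73, a description of the genes, which are not independent replicates.

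Some genes, TNF and CCL5 among them, set the treatments apart. The difference of the effects was tested directly, and negative values mean a larger rise, or a smaller fall, with the acp3U-8C fragment. TNF gave -2.49, CCL5 -1.99, IDO1 -2.16, IFNL1 -1.81, GCH1 -1.70, IL27 -1.35 and CXCL9 -1.24, while CXCL10 (0.13) and IFNB1 (-0.49) were not called. In the chemokine list 10 of 18 genes differed toward acp3U-8C and none the other way (camera adjusted p = 3.37e-13; adjusted p = 0.234 with an estimated correlation), in the inflammatory cytokine list 6 of 14 and none (camera adjusted p = 1.29e-06; adjusted p = 0.149 with an estimated correlation), and in the NF-kB list 7 of 27 and 1 (camera adjusted p = 1.81e-06; adjusted p = 0.234 with an estimated correlation). The interferon-stimulated list also passed toward acp3U-8C, with 4 of 45 genes that differed that way and none the other way (camera adjusted p = 0.0235; adjusted p = 0.635 with an estimated correlation). In the MHC class I list 1 of 20 differed. Rises larger with PNGase F were those of CD163 (0.79), FCGR1A (0.70), BCL3 (0.49), SECTM1 (0.48), TASL (0.40) and TAP2 (0.33).

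In all, limma called 479 genes at a Benjamini-Hochberg adjusted p under 0.05 for a difference of the 2 effects, 285 toward acp3U-8C and 194 toward PNGase F, of which 79 and 9 differed by at least 1 log2 unit. Camera passed 12 lists, 8 toward acp3U-8C and 4 toward PNGase F, and none held with an estimated correlation. Besides the lists above, those toward acp3U-8C were immediate early genes (5 of 24, adjusted p = 0.234 with an estimated correlation), the unfolded protein response (1 of 20, adjusted p = 0.234 with an estimated correlation), dendritic cell markers (2 of 8, adjusted p = 0.385 with an estimated correlation) and MHC class II (0 of 9, adjusted p = 0.234 with an estimated correlation). Those toward PNGase F were cholesterol biosynthesis, which fell less with PNGase F than with acp3U-8C (2 of 20, adjusted p = 0.234 with an estimated correlation), alternative activation (1 of 9 each way, adjusted p = 0.234 with an estimated correlation), heat shock proteins (0 of 14, adjusted p = 0.385 with an estimated correlation) and mitochondrially encoded mRNAs (0 of 13, adjusted p = 0.573 with an estimated correlation). Adjusted over the list alone, 12 chemokines, 7 cytokines, 10 NF-kB genes, 10 immediate early genes and 5 interferon-stimulated genes differed toward acp3U-8C, and 6 cholesterol genes, 6 alternative activation genes and 2 heat shock genes toward PNGase F. So did 1 cytokine, while 2 cholesterol genes, 1 alternative activation gene and 1 MHC class II gene differed toward acp3U-8C, and the counts of the other passing lists and of NF-kB genes toward PNGase F were equal. The count of 479 was 156 without a filter and 315 with TPM, where 16716 genes passed the filter, and it fell whichever library was left out. It was 210 and 182 without untreated small RNA replicates 1 and 2, 172 and 224 without PNGase F replicates 1 and 2, 206 and 269 without unmodified fragment replicates 1 and 2, and 193 and 184 without acp3U-8C replicates 1 and 2. The amounts of RNA transfected are not given in the sources used here, so the sizes of the 2 effects are not set against a common dose.

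**Figure D3:**
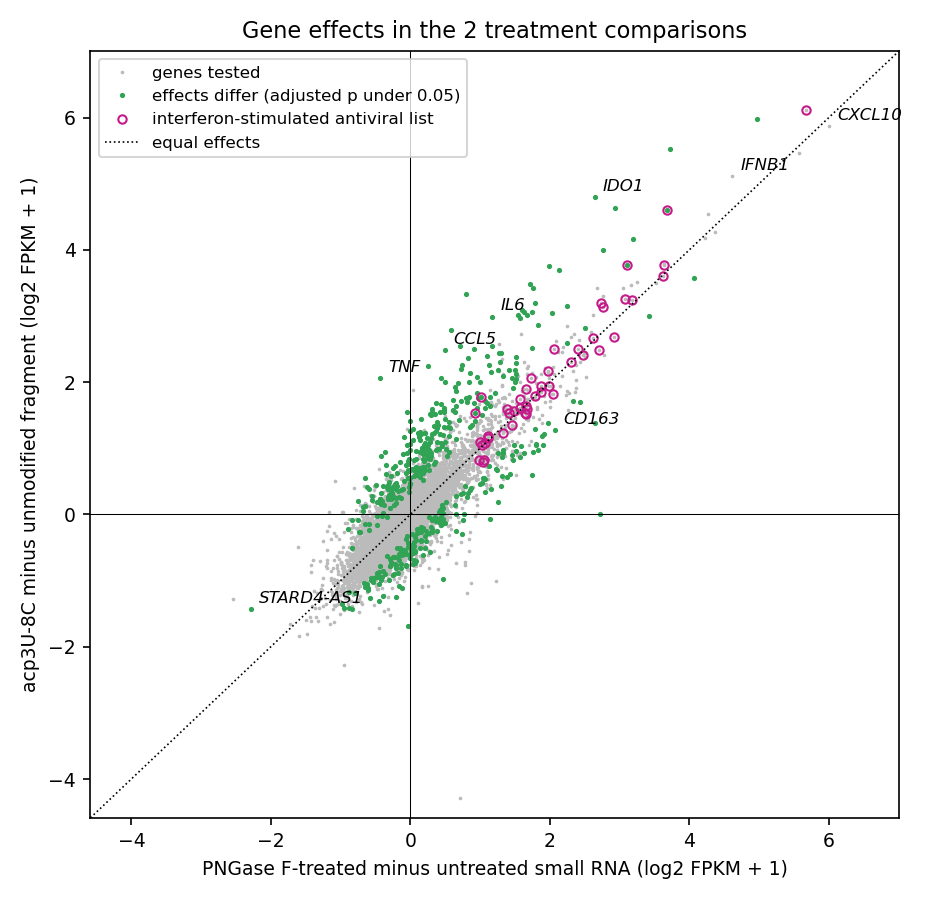
Each point is 1 of 13223 genes, with its log2(FPKM + 1) difference for PNGase F-treated against untreated small RNA on the x axis and for the acp3U-8C against the unmodified fragment on the y axis. Green points are the 479 genes whose effects differed, circles mark the interferon-stimulated antiviral list, and TNF lies at -0.43 and 2.06.

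The reference RNAs themselves were compared last, as a secondary comparison, since no sample without transfected RNA was analysed here. Cells given the unmodified fragment had more of some interferon-stimulated transcripts than cells given untreated small RNA, although less than either treated group for the genes given here. MX1 stood at 61.9 ± 0.995 against 19.4 ± 0.886 FPKM (mean ± SD, n = 2; log2 difference 1.62), CXCL10 at 20.7 ± 2.67 against 6.83 ± 0.0241 FPKM (1.47), and IFNB1 at 1.62 ± 0.360 against 0.639 ± 0.255 FPKM (0.68). The single largest increases were those of FABP4, a fatty acid carrier of macrophages (2.01), the stress-inducible HSPA6 (1.76), ADCY8 (1.68), BCL2L2-PABPN1 (1.67) and the CCDC39 entry named above, which was listed at 0 in 1 of the untreated small RNA libraries, had 0.0408 FPKM in the other and a mean of 2.21 FPKM with the unmodified fragment. The largest decreases were those of ENSG00000267598 (-2.42), LINC01140 (-2.20), the aldo-keto reductases AKR1C2 (-2.18) and AKR1C3 (-2.12), and SLC9A3-AS1 (-1.94). BCL2L2-PABPN1 is a readthrough of neighbouring genes, AKR1C2 and AKR1C3 are close copies of each other, and ENSG00000267598 and SLC9A3-AS1 are antisense transcripts, so these values are uncertain.

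Of the interferon-stimulated list 19 of 45 genes rose and 2 fell (camera adjusted p = 1.64e-06; adjusted p = 0.453 with an estimated correlation), with IFIT2 at 1.02 and IFITM1 at 0.96, while IFIT1 (0.23) was called and ISG15 (0.13) was not. The IFIT1 call was lost on leaving out any 1 library of the untreated small RNA (0.27 without replicate 1 and 0.19 without 2), unmodified fragment (0.28 and 0.18) or acp3U-8C group (0.23 and 0.23). Of the chemokines 8 of 18 rose and none fell. Examples were CXCL11 at 0.99, CCL3 at 0.89 and CCL3L1, a close copy of CCL3, at 1.13 (camera adjusted p = 0.000394; adjusted p = 0.38 with an estimated correlation). Of the heat shock proteins 11 of 14 rose and 1 fell. Examples were HSPA1B at 0.73, HSPA1A at 0.69 and HSPH1 at 0.56 (camera adjusted p = 3.35e-06; adjusted p = 0.38 with an estimated correlation). Of the lysosome genes 12 of 27 rose and 4 fell. Examples were CTSD at 0.99, CTSZ at 0.82 and GPNMB at 0.52 (camera adjusted p = 0.00203; adjusted p = 0.38 with an estimated correlation). Metallothioneins and NRF2 targets (9 of 15 rose, 1 fell; HMOX1 at 0.57, FTL at 0.54, NQO1 at 0.41 and GCLC at -0.71) and MHC class II genes (4 of 9 rose; HLA-DRB5 at 1.12, CD74 at 0.55, HLA-DRB1 at 0.55 and HLA-DQB1 at 0.38) passed as well (adjusted p = 0.38 with an estimated correlation for each). The mitochondrially encoded mRNAs passed upward with 3 of 13 called, MT-ND1 (0.38), MT-CYB (0.35) and MT-ND2 (0.25) (adjusted p = 0.652 with an estimated correlation). The ribosomal proteins passed downward with 7 of 38 called, among them RPL19 (-0.28), RPS19 (-0.37), RPS27 (-0.28) and RPS18 (-0.31) (adjusted p = 0.5 with an estimated correlation). Some calls in the last 3 of these lists were lost with a library left out. HLA-DQB1 lost its call without untreated small RNA replicate 1 (0.44) or 2 (0.32) and without unmodified fragment replicate 1 (0.38) or 2 (0.37). RPS19 lost it without untreated small RNA replicate 1 (-0.30) or unmodified fragment replicate 2 (-0.32), RPS27 without replicate 1 of either group (-0.22 and -0.23), and RPS18 without untreated small RNA replicate 1 (-0.30) or 2 (-0.32) or unmodified fragment replicate 1 (-0.25). MT-ND1 lost it without untreated small RNA replicate 2 (0.35), MT-CYB without untreated small RNA replicate 1 (0.34) or 2 (0.35), and MT-ND2 without these (0.28 and 0.23) or unmodified fragment replicate 1 (0.16). MT-ND3 was called only without unmodified fragment replicate 2 (0.19) among the libraries left out. The mitochondrial list kept its call only without untreated small RNA replicate 1 or unmodified fragment replicate 2, and its adjusted p was 0.0752 without untreated small RNA replicate 2, 0.431 without unmodified fragment replicate 1, 0.0575 and 0.0581 without PNGase F replicates 1 and 2, and 0.0558 and 0.0557 without acp3U-8C replicates 1 and 2. It also missed with the filter of 5 FPKM (0.0545), quantile normalization (0.352), the 4 libraries of the comparison (0.0876), moderation without trend (0.071) and fry (0.159). The MHC class II list missed with the filter of 5 FPKM (0.0545), and the ribosomal list with quantile normalization (0.0558) and fry (0.0894). Without a filter the calls of HLA-DQB1, RPS19, RPS27, RPS18, MT-ND1, MT-CYB, MT-ND2 and IFIT1 were lost.

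IL1B fell by 0.49 with the unmodified fragment (limma, Benjamini-Hochberg adjusted p = 0.000338), and MERTK rose by 0.22 (limma, Benjamini-Hochberg adjusted p = 0.046), a call lost on leaving out any 1 library of the untreated small RNA (0.18 without replicate 1 and 0.26 without 2), unmodified fragment (0.22 and 0.22) or acp3U-8C group (0.22 and 0.22). It was also lost without a filter, with TPM, with the 4 libraries of the comparison, with moderation without trend and with the replicate block. TNF was not called (0.26) but was called without untreated small RNA replicate 1 (0.38), with the filter of 5 FPKM (0.26) and with quantile normalization (0.28). CCL5 (-0.15), TLR7 (-0.13), TLR8 (0.28) and CD36 (-0.09) were not called, although TLR8 was called with a pseudocount of 0.1 (0.66) or 0.01 (0.78), on rescaling to TPM (0.47) and with moderation without trend (0.28). TLR3 lay below the filter at 0.212 FPKM, and IL6 was listed at 0 in 3 of the 4 libraries. The calls numbered 3158 in limma at a Benjamini-Hochberg adjusted p under 0.05, 1618 higher and 1540 lower, of which 64 and 61 differed by at least 1 log2 unit, and the median gene did not shift (0.00). The count was 1716 and 1766 without untreated small RNA replicate 1 and replicate 2, and 1987 and 2038 without unmodified fragment replicate 1 and replicate 2. Of 32 lists 8 passed camera, 7 upward and 1 downward, and none held with an estimated correlation. Adjusted over the list alone, 23 interferon-stimulated genes, 9 chemokines, 12 heat shock genes and 11 metallothionein and NRF2 genes rose, 2 ribosomal protein genes fell, and the counts of the MHC class II, lysosome and mitochondrial lists were equal.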

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

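The tests in this part were set out ahead of the values they measure, except the tests with quantile normalization and of how far the scaling moved the differences, which were chosen after the result was seen. A direct test of whether the PNGase F effect and the acp3U-8C effect differ picked out 479 genes, and those below are the ones among them that the naming rule had put in the report. Values are the PNGase F effect minus the acp3U-8C effect on the log2(FPKM + 1) scale, so negative values mean a larger rise, or a smaller fall, with the acp3U-8C fragment.

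Toward acp3U-8C stood TNF (-2.49), IDO1 (-2.16), CCL5 (-1.99), IL6 (-1.82), IFNL1 (-1.81), CCL3L1 (-1.77), GCH1 (-1.70), IL27 (-1.35), CXCL9 (-1.24), CXCL11 (-1.01), CCL3 (-0.997), GCLC (-0.95), HERC5 (-0.92), STARD4-AS1 (-0.86), LAMP3 (-0.84), NFKBIZ (-0.77), PTGS2 (-0.77), IL1B (-0.76), KLF4 (-0.74), DUSP5 (-0.63), JUNB (-0.48), XBP1 (-0.47) and IFIH1 (-0.34). TNF fell by 0.43 with PNGase F and rose by 2.06 with acp3U-8C, while STARD4-AS1 fell with both. IL6 was listed at 0 in both untreated small RNA libraries, so its value depends on the pseudocount. IL1B and GCLC were lower with the unmodified fragment than with untreated small RNA, and they differed less between the treated groups than between these references. Their values therefore reflect the reference levels more than the treated levels.

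Toward PNGase F stood CCDC39 (1.65), CD163 (0.79), FCGR1A (0.70), UHRF1 (0.69), MVK (0.50), BCL3 (0.49), SECTM1 (0.48), MERTK (0.48), MCM4 (0.40), TASL (0.40) and TAP2 (0.33). CCDC39 was listed at 0 in 5 of the 8 libraries, which included both PNGase F and both acp3U-8C libraries, so its value describes the unmodified fragment libraries alone.

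For the differing genes, 2 technical explanations were considered. If the 2 reference groups simply started at different levels, the differing genes would differ more between the references than between the treated groups, but only 19.6% (94 of 479) did. Under median-of-ratios scaling 93.9% (450 of 479) were still called in the same direction. That scaling moved the median difference by only 0.018, where the smallest called difference was 0.27, so it could hardly have ended these calls. Quantile normalization left 449 of the 479. It ended 32.9% of the PNGase F calls, where the median gene was shifted by -0.19. That shift was nearly equal with acp3U-8C (-0.20), so the median difference of the effects was only 0.02. The lost PNGase F calls therefore do not show that quantile normalization could have ended the differing calls. Rescaling to TPM, where 16716 genes passed the filter, left only 311. These counts describe how far the calls depended on the scalings tried, and they do not exclude the scaling of the FPKM as a cause. Open is the amount and the delivery of each RNA, which the labels do not give and which may differ between small RNA and a synthetic fragment. A property of the RNA itself is the biological alternative, and it was not tested.

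The downward shift of most genes, with medians of -0.19 and -0.20, was the second pattern weighed. Gene length bias would leave some length class without a shift, but the highest median among 5 length classes was -0.16 with PNGase F and -0.17 with acp3U-8C. For a few strongly induced genes taking up the library, the 100 genes of largest gain were taken out and each library was rescaled to the same FPKM sum. Of the shift 54.1% and 45.0% was left. The FPKM sums were lower in the treated libraries before this step, so the rescaling itself removed part of the shift. The genes called higher held 9.93% of the FPKM sum with untreated and 17.6% with PNGase F-treated small RNA. They held 9.66% with the unmodified and 19.3% with the acp3U-8C fragment. All other genes together thus took up less of the treated libraries, which goes with a downward shift. The genes called higher were chosen by their rise, and the part of the shift they account for was not computed. Loss of cytosolic mRNA that spares mitochondrial transcripts cannot be told apart from other causes, because the mitochondrial list had medians of -0.033 and -0.19 in the 2 comparisons. FPKM are relative to each library, so a fall in the total mRNA of the cells stays untested.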

How the results depend on the processing

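The alternatives were all planned. Of the values of named genes, 2764 kept their direction and their side of the threshold, 27 lost and 28 gained a call, and 3 reversed, all CD36. With single libraries left out these numbers were 1839, 34, 11 and 2. Many of the named genes were chosen for large, called changes in these data, so their calls were likely to hold. Leaving out a library that a comparison does not use left its log2 differences unchanged and altered only the spread and the genes tested. Of the gene list results 553 held and 62 lost their call, and 335 and 17 with single libraries left out. Leaving out a library leaves a lone sample, which is assumed to vary like the other groups. The replicate block gave 6865, 7737 and 3009 genes for PNGase F, acp3U-8C and the reference RNAs, and 339 for the difference of effects, although replicate numbers do not pair here (correlations of replicate deviations -0.03 to 0.05).

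For the correlation of the 2 treatments' log2 differences across genes (0.85), pseudocounts of 0.1 and 0.01 gave 0.825 and 0.804, no filter 0.808, the stricter filter 0.892, TPM 0.783, the 4 libraries of each comparison 0.869, and single libraries left out 0.835 to 0.848. For the genes whose change differs between the 2 treatments (479), no filter gave 156, TPM 315 and single libraries left out 172 to 269, the latter with fewer samples. For PNGase F, median-of-ratios scaling gave 4562 genes in place of 6920. For the reference RNAs, single libraries left out gave 1716 to 3124 genes in place of 3158.

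For gene lists, an estimated correlation left 2 of 18 with PNGase F, 6 of 18 with acp3U-8C and 0 of 8 for the reference RNAs. These losses do not measure correlation alone. With PNGase F the cytokine, alternative activation and histone lists had estimated correlations of -0.022, -0.049 and -0.11, below the preset 0.01. Their unadjusted camera p still rose from 0.000695, 0.000701 and 0.0151 to 0.0226, 0.0244 and 0.0666. The rotation test fry, which does not rank a list against other genes, gave 28 with PNGase F and 21 for the reference RNAs, and no filter gave 15 for the reference RNAs. CD36, which was not called, reversed with PNGase F from -0.01 to 0.19 with median-of-ratios scaling and 0.037 with TPM, and ranged from -0.068 to 0.043 with single libraries left out. In the acp3U-8C comparison it went from -0.08 to 0.14 with median-of-ratios scaling. Median-of-ratios scaling also moved the median gene upward, from -0.19 to -0.02 with PNGase F and from -0.20 to -0.02 with acp3U-8C. The CD36 reversals with that scaling therefore go with a shift of genes in general. Apart from this and the smaller sample, causes were not tested. Depth limits low genes, since the least deep library, acp3U-8C replicate 1, had 54.2% of the depth of the first untreated small RNA library.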

Other observations

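The families in this part were chosen after their values were seen, and the test on HeLa transcripts was set out ahead of its value, except that the comparison of keratin levels with the falls was chosen after. Guanylate-binding proteins rose in 5 of 5 genes with both treatments, with medians of 3.42 (PNGase F) and 4.16 (acp3U-8C). Apolipoprotein L genes rose in 4 of 5 with PNGase F (5 with median-of-ratios scaling) and 5 of 5 with acp3U-8C. All 6 Fc gamma receptor genes rose in both, with medians of 1.63 and 1.09, and 3 of the 6 differed toward PNGase F. The 4 genes of the CCL3 and CCL4 group rose in both with medians of 0.98 and 2.94, and all 4 differed toward acp3U-8C. These counts were equal with median-of-ratios scaling except where given.

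Of 10 caspase genes 7 rose and 1 fell with PNGase F, and 7 rose and 2 fell with acp3U-8C (1 fell when scaled). Of 17 genes of the 20S proteasome 6 rose and 1 fell with PNGase F, and 6 rose and 3 fell with acp3U-8C, while with median-of-ratios scaling 11 rose and none fell in each. Of 321 zinc finger genes named ZNF, 159 fell in each comparison, with 10 and 13 that rose. Falls were also common among all 13223 genes tested, of which 5267 and 5887 fell. The ZNF medians were -0.31 and -0.29, against -0.19 and -0.20 for all genes. With scaling 61 and 78 ZNF genes fell and 19 rose in each, while 2024 and 2624 of all genes fell.

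A pair of entries for MATR3 moved in opposite directions with acp3U-8C (1.28 for ENSG00000015479 and -1.21 for ENSG00000280987), and their sum changed by -0.30, so neither value stands for the gene.

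Messenger RNA of the HeLa source cells carried along in the small RNA was considered as a source of transcripts lower with the unmodified fragment. It would make epithelial markers lower with the unmodified fragment, but the median of the 8 tested markers of 28 was 0.18, from -0.25 for CAV1 to 0.89 for AXL. Only markers that passed the expression filter entered this median, which KRT8 and KRT18 did not, so it cannot rule out traces of HeLa RNA. HeLa RNA would also bring its abundant keratin transcripts, yet KRT8 and KRT18 reached at most 0.202 FPKM with untreated small RNA, while the 1540 genes lower with the unmodified fragment fell by at least 0.414 FPKM (median 3.60). These values argue against it as the cause of those falls as a whole, and a small share is not excluded. CAV1 had 2.03 and 2.47 FPKM with untreated small RNA and 1.71 and 1.75 FPKM with the unmodified fragment. KRT8 had 0.113 and 0.202 FPKM with untreated small RNA and 0.254 and 0.223 FPKM with the unmodified fragment, and KRT18 had 0.0473 and 0.0472 against 0 and 0.0147 FPKM. AXL, 1 of the 28, also stands in the apoptotic cell uptake list.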
